A study of Bacillus subtilis subsp. subtilis NCIB 3610 = ATCC 6051 = DSM 10 with 2 samples.

How the data were processed

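Genomic DNA of Bacillus subtilis NCIB 3610, the ancestral strain that carries the large plasmid pBS32, was sequenced from a wild-type strain and from a strain lacking rnhP and rnhC. Each genotype is represented by 1 sample, and each sample has 1 depth table for the chromosome and 1 for the plasmid. The tables give a signal for every base, the read depth or coverage, in 3 columns of whole numbers and a further column that the authors deposited as their average. The average column equalled the mean of the 3 columns at every base to within 0.0033 reads. The labels do not say whether the 3 columns are separate cultures, separate libraries or repeated runs. They were therefore treated as 3 measurements of 1 sample, the spread between them is given as an SD over columns, and no p-value was computed.

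The submitters' processing notes name BWA 0.7.8-r455, Picard, SAMtools 0.1.18 and bedtools 2.29.1, without the role or order of each. The DNA was extracted with the MasterPure Gram Positive kit, per the labels. Positions are those of the sequences named in the files, of 4215607 bases for the chromosome and 84215 bases for the plasmid. The deposited signal columns hold whole numbers whose totals differ between columns, so they were taken as not scaled to library size. The mapping rules and the handling of duplicate reads are not given in the sources used here, and the following properties were read from the values.

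Changes of depth from base to base were most strongly opposed at a lag of 76 bases in all columns of both replicons, among lags up to 399 bases, which is the trace of a fixed read length of 76 bases. Depth levelled off near 152 reads, or 1 read per start position on each strand, and passed 160 reads only at the ends of the linear sequences and at the edges of a lost stretch. Over the wild-type plasmid the first column had a mean depth of 129.9 with an SD over bases of 4.82, where random reads without a ceiling would give 11.4 and filling of start positions at random would give 4.35. Deposited depth was therefore taken as the number of occupied start positions, which is compressed where copy number is high. Depth was converted to the number of reads per start position and strand before such a ceiling as −ln(1 − depth/152), from the mean depth of a region over bases with a depth of at least 20 in all 6 columns. These bases made up 98.56% of the chromosome and 99.48% of the plasmid. Mean depth was capped at 1 read below 152 before conversion, which limits the highest values. The conversion assumes that reads start evenly within a region, and uneven starts make it an underestimate. It was chosen after seeing the data and is called converted depth.

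Dividing total depth by the read length gives 6431431, 7315127 and 7387038 reads in the 3 wild-type columns and 7089509, 7143373 and 7427019 reads in the 3 deletion columns. On the chromosome, 74.57% to 86.22% of start positions were occupied, and on the plasmid 85.44% to 93.44%. The 95% Wilson interval was 74.54% to 74.60% for the lowest of these shares on the chromosome and 93.32% to 93.56% for the highest on the plasmid. Intervals and detection limits cover counting error only, and the spread between columns was much larger.

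A lost stretch was a run of bases with a depth of 0 in at least 2 columns of 1 genotype and of at least 20 in all columns of the other. The share of reads left in it was set against the number expected at the wild-type level, with an exact Poisson interval. A count of 0 allows up to 3 reads. The plasmid to chromosome ratio was the median depth of the plasmid over that of the chromosome. The origin to terminus ratio was the median depth of the 100 kb around the start of the chromosome sequence over that of the 100 kb around its midpoint at 2.108 Mb. Windows of 1 kb on the chromosome and 500 bp on the plasmid were compared after scaling each library to the median of that replicon, if either library had a median depth of at least 10 in the window. Changes of at least 2-fold were counted. Slopes of log2 depth along each arm were fitted by least squares over 10 kb windows. Unevenness was the coefficient of variation over 1 kb windows, on the chromosome after dividing by a running median over 201 kb. The ratios, windows, slopes, unevenness and their alternatives were set before the data were examined. Values of deposited depth for a genotype come from the average column, except slopes and steps. Slopes, steps and values of converted depth for a genotype are means over the 3 columns. Alternatives were other window and region sizes, means in place of medians, other scalings, no depth minimum, a 1.5-fold threshold and each column alone. The rule for naming features was the deleted genes first and then, by size alone, genes and runs of windows changed at least 2-fold, with windows by position where no annotation of the same assembly is used. The 10 kb and 100 kb profiles of converted depth and the step near the terminus were added after seeing the data.

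The gene table used here is of another assembly of this strain, ASM608879v1, with other coordinates. It was used only for names, counts and neighbours, so windows are given by position. The planned comparisons of gene lists, of genes read with or against replication, and of base composition need the same assembly and were not run, and the midpoint stood for the terminus in place of the gene rtp. The statistics were tested on simulated reads with a known copy number profile and a depth ceiling. Of 200 simulated 1 kb windows of 4215 in which copy number was raised 2-fold, 0% passed 1.5-fold in depth and 100% passed it in converted depth. Of 200 windows in which it was lowered 2-fold, 4% passed 1.5-fold in depth and 100% in converted depth. The simulated reads started evenly and each change filled a whole window, so these shares may overstate detection in the real depth. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.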

Results

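DNA sequencing depth was measured across the chromosome and the plasmid pBS32 of Bacillus subtilis NCIB 3610. A wild-type strain was compared with a strain lacking rnhP and rnhC. RNase H enzymes cut the RNA strand of RNA-DNA hybrids. RnhC is the RNase HIII encoded on the chromosome, and RnhP is an RNase HI encoded on pBS32. There was 1 sample per genotype, with 3 depth columns in each, so differences between genotypes have no check by separate samples and no p-value is given. The median depth of the chromosome was 128 reads per base in the wild type and 131 in the deletion strain. The median depth of the plasmid was 138 and 142 reads per base. The question set by the design was how coverage of both replicons compares between the genotypes.

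Each replicon of the deletion strain had 1 stretch of lost DNA. On the chromosome, depth was absent, or close to it, from position 2926053 to 2926983, a stretch of 931 bases. On the plasmid the stretch ran from 62049 to 62487, over 439 bases. The wild type had a depth of 97.1% of the chromosome median over the first stretch and 98.8% of the plasmid median over the second. In the deletion strain the values were 0.021% and 0.079%. No stretch of either replicon was covered in the deletion strain and empty in the wild type. The labels name rnhP and rnhC as deleted, but neither stretch was matched to a gene by position, since the gene table used here belongs to another assembly of the strain. In that table rnhC lies between zapA, whose product acts in cell division, and pheT, which encodes a subunit of phenylalanyl-tRNA synthetase.

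The lost stretches were not fully free of reads. On the chromosome, deletion column 1 had 1 read, 0.068% of the 1479 expected at the wild-type level (exact 95% Poisson interval 0.0017% to 0.377%). On the plasmid, deletion column 2 had 2 reads, 0.249% of the 804 expected (0.030% to 0.898%). The other columns had 0 reads, which allows a share of up to 0.190% and 0.185% in columns 2 and 3 on the chromosome, and up to 0.372% and 0.370% in columns 1 and 3 on the plasmid. The stretches were themselves bounded by a depth of 0 in at least 2 columns, so these shares are not an independent measure of reads left. At both edges of the plasmid stretch, depth in all 3 deletion columns exceeded 160 reads, with maxima of 161 to 172. The wild-type columns passed 160 reads on the plasmid only at the ends of the sequence.

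**Figure D1:**
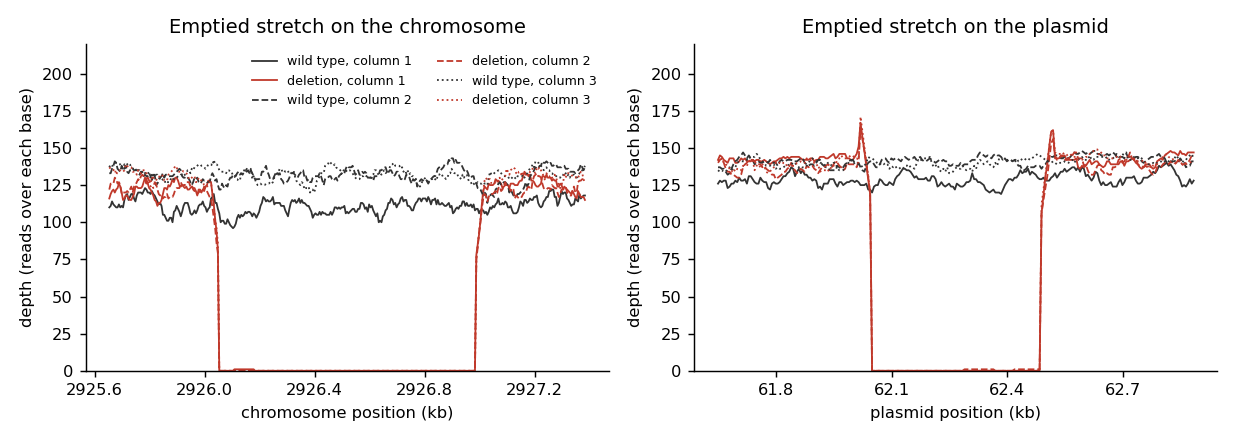
Depth in reads over each base (y axis) against position in kb (x axis) around the stretch lost on the chromosome (left) and on the plasmid (right) (1 base in 5 drawn). Black lines are the 3 wild-type depth columns and red lines the 3 deletion columns. Depth falls to 0 or 1 read across 931 bases of the chromosome and 439 bases of the plasmid in the deletion strain only.

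Plasmid pBS32 had about the same depth relative to the chromosome in both strains. The plasmid to chromosome depth ratio was 1.08 ± 0.036 (SD over 3 columns) in the wild type and 1.08 ± 0.029 in the deletion strain. The ratio of these ratios was 1.00 ± 0.043, and the ranges of the columns overlapped. Both replicons lay near the depth ceiling of 152 reads, which draws such ratios towards 1. With converted depth the plasmid ratio was 1.35 ± 0.032 in the wild type and 1.41 ± 0.093 in the deletion strain, a mean over columns that was 1.05 ± 0.074 times as high. The wild-type columns gave 1.37, 1.36 and 1.31, and the deletion columns gave 1.52, 1.37 and 1.35. A change of plasmid copy number within that spread was not detectable.

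Set against single regions of the chromosome, the plasmid lay between the origin and the terminus. Its converted depth was 0.86 ± 0.060 times that of the 100 kb around the origin in the wild type and 0.95 ± 0.025 times in the deletion strain. Relative to the 100 kb around the midpoint of the chromosome it was 2.18 ± 0.10 times as high in the wild type and 2.31 ± 0.16 times in the deletion strain. The ranges of the columns overlapped relative to the midpoint region. They barely did so relative to the origin, where the lowest deletion column, 0.928, lay just below the highest wild-type column, 0.930.

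Within the plasmid, the lost stretch held the only window with a change of at least 2-fold. Depth as deposited is evened out by the ceiling here, since 85.44% to 93.44% of start positions were occupied. The coefficient of variation of deposited depth over 1 kb windows was 0.93% in the wild type. In the deletion strain it was 4.88%, and 0.88% without the window that holds the lost stretch. Of 168 windows of 500 bp, 1 fell at least 2-fold in the deletion strain and 0 rose. The lowered window, 62001 to 62500, had a mean depth of 136 in the wild type and 16.4 in the deletion strain. The next lowest, 51501 to 52000, was at 0.978 times the wild type, and the highest, 18001 to 18500, was at 1.02 times. The log2 ratios had a 1st to 99th percentile range of −0.032 to 0.025 as deposited and a wider one of −0.13 to 0.11 in converted depth. In converted depth, 0 of 167 windows passed 1.5-fold in either direction. Changes were simulated in chromosome windows only, so detection on the plasmid was not tested.

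Depth fell from the origin of replication to the terminus in both strains. Replication of this circular chromosome runs from the origin along both arms, so origin DNA outnumbers terminus DNA in growing cells. The median depth around the origin was 143 in both strains. Around the midpoint it was 102 in the wild type and 105 in the deletion strain. The origin to terminus ratio was 1.40 ± 0.14 (SD over 3 columns) in the wild type and 1.36 ± 0.061 in the deletion strain, and the deletion strain had 0.97 ± 0.11 times the wild-type ratio. With converted depth the ratios were 2.54 ± 0.24 and 2.44 ± 0.23, so the conversion raised them by more than 1.5 times while the deletion strain stayed at 0.96 ± 0.13 times the wild type. The ranges of the columns overlapped on both scales.

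**Figure D2:**
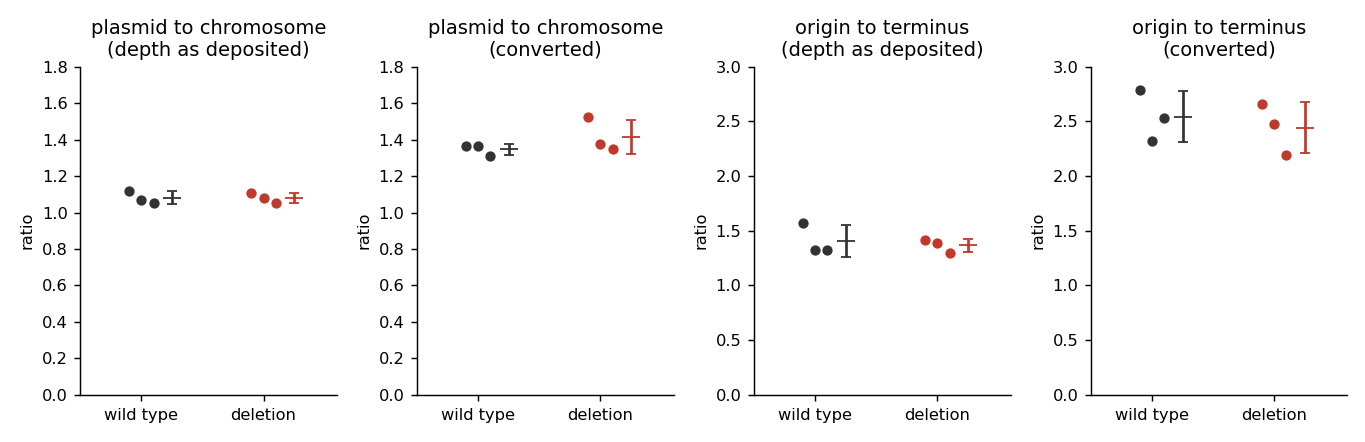
Plasmid to chromosome ratio and origin to terminus ratio (y axes, ratios without a unit) in the wild type and the deletion strain, from depth as deposited and from converted depth. Points are the 3 depth columns of each sample, and bars are their mean and SD. The columns of both strains overlap in every panel, and origin to terminus ratios are near 1.4 as deposited and near 2.5 after conversion.

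On the chromosome, the lost stretch gave the only 1 kb window with a change of at least 2-fold. Of 4162 windows of 1 kb, 1 fell at least 2-fold in the deletion strain, from 2926001 to 2927000, where mean depth was 124 in the wild type and 6.82 in the deletion strain. No window rose by 2-fold or by 1.5-fold. Outside the lost stretch the windows ranged from 0.833 times the wild type, at 2266001 to 2267000, to 1.15 times, at 1966001 to 1967000. The interquartile range of log2 ratios over windows was −0.031 to 0.024, a spread along 1 pair of samples. In deposited depth, 0% of simulated 2-fold gains and 4% of simulated 2-fold losses passed 1.5-fold, so these counts say little about gains or about losses short of missing DNA. In converted depth, 0 of 4161 windows passed 1.5-fold in either direction. There 100% of both simulated changes passed 1.5-fold, with reads that started evenly. The count is over the 3 columns together and does not describe single columns. Over 2260001 to 2270000, deletion column 2 was at a log2 of −0.59 and columns 1 and 3 at −0.19 and −0.041.

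Over longer distances the arm that runs from the origin towards higher positions, called clockwise here, was higher in the deletion strain next to the terminus. The 100 kb from 1900001 to 2000000 had a converted depth 1.19 times that of the wild type after scaling to the chromosome. This was a log2 difference of 0.25 ± 0.014 (SD over 3 deletion columns). That SD leaves out the spread between the wild-type columns. From 1 to 600000 the 100 kb regions lay between 0.973 and 1.01 times the wild type. From 600001 to 1900000 the 100 kb regions lay between 1.03 and 1.15 times the wild type. From 2100001 to 4200000, on the other arm, they lay between 0.896 and 0.990 times. The values are relative to the whole chromosome, so a gain in some regions lowers the others. The 10 windows of 10 kb with the highest ratio all lay between 1910001 and 2020000, and the highest, 1980001 to 1990000, was at 1.23 times.

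This excess fell beyond 2.019 Mb. In the 10 kb windows that start at 2010001, 2020001, 2030001 and 2040001 it was a log2 of 0.26, 0.15, 0.086 and 0.047. Every deletion column lay above every wild-type column in the first 3 of these windows but not in the last. In the windows that start at 2050001 and 2060001 the log2 difference was −0.014 and −0.19. Regions on either side were chosen after the profile had been seen, 1.91 to 2.01 Mb and 2.03 to 2.13 Mb. In the deletion strain the clockwise region had 1.24 times the converted depth of the other, a log2 step of 0.31 ± 0.051 (SD over 3 columns, with 0.28, 0.37 and 0.28 in the columns). In the wild type the step was 0.048 ± 0.010, with 0.055, 0.053 and 0.037 in the columns. The strains differed by 0.26 ± 0.052, and the ranges of the columns did not overlap. In depth as deposited the steps were 0.15 ± 0.032 and 0.027 ± 0.0084. The best single change of level between 1.97 and 2.07 Mb lay after position 2019000, 2020000 and 2019000 in the deletion columns. In the wild-type columns it lay after 2015000, 2019000 and 2059000. These positions come from the depth of each column alone and do not locate the difference between strains. In a search along the chromosome, the largest step of that difference, a log2 of 0.268, was centred at 2.035 Mb. Both strains had a local drop of deposited depth near 2.019 Mb. Between the 2 kb windows that start at 2016001 and 2020001 depth went from 85.7 to 80.0, 110.7 to 103.8 and 112.0 to 105.4 reads in the wild type and from 112.2 to 102.5, 114.5 to 105.4 and 121.2 to 110.6 reads in the deletion strain. In the window that starts at 2040001 the wild-type columns were at 85.4, 107.3 and 111.1 reads and the deletion columns at 106.3, 103.3 and 111.4. The wild-type columns had thus regained more of their drop than the deletion columns.

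The fall of depth along each arm, split at the midpoint, overlapped between the strains, while the difference between the arms did not. In depth as deposited the clockwise slope was −0.24 ± 0.079 log2 per Mb (SD over 3 columns) in the wild type and −0.18 ± 0.042 in the deletion strain. The slope of the other arm was −0.23 ± 0.077 and −0.21 ± 0.033. The clockwise slope minus the other was −0.012 ± 0.0034 in the wild type and 0.035 ± 0.0089 in the deletion strain. In converted depth the clockwise slopes were −0.69 ± 0.065 and −0.59 ± 0.088, and those of the other arm −0.65 ± 0.068 and −0.62 ± 0.057. The differences between arms were then −0.037 ± 0.0076 and 0.033 ± 0.032. With the arms ending at 2.01 and 2.03 Mb, limits chosen after seeing the data, they were −0.022 ± 0.011 and 0.066 ± 0.047. In depth as deposited with these limits the differences were 0.00465 ± 0.0048 and 0.059 ± 0.013, so the wild-type sign depended on the limits.

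**Figure D3:**
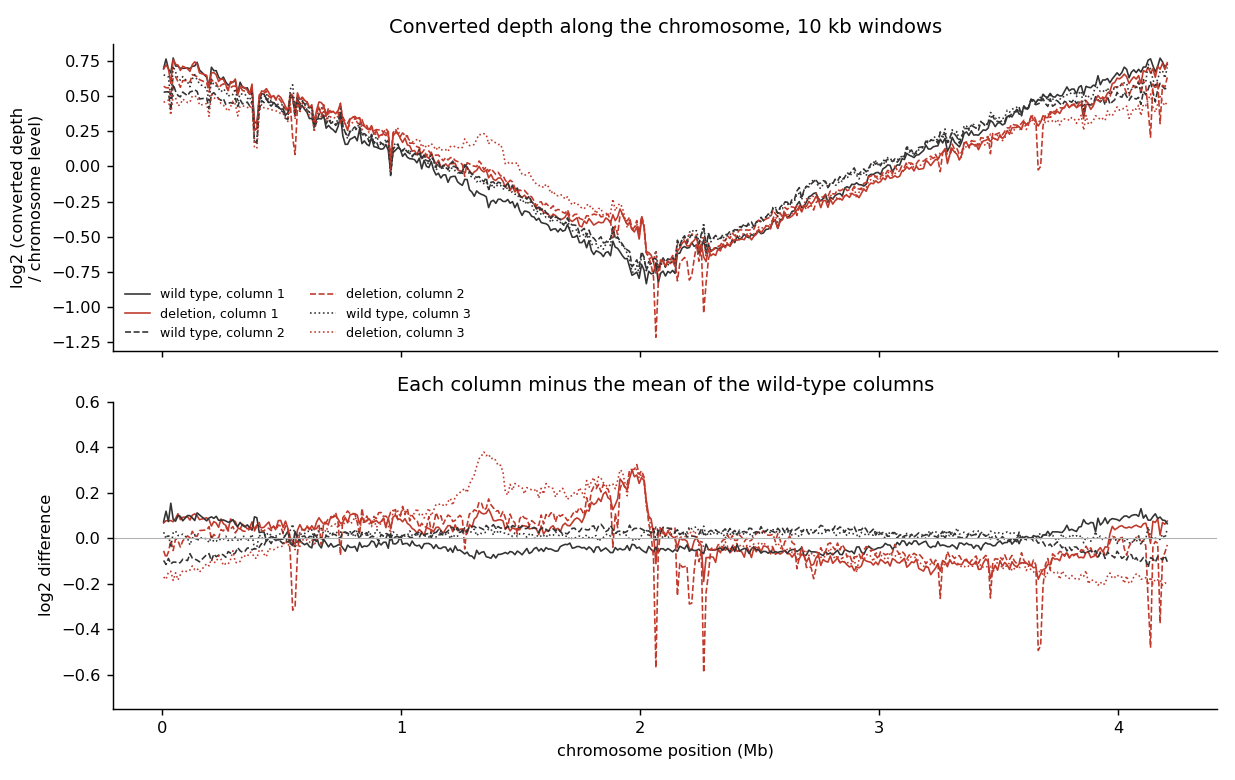
Log2 converted depth relative to the chromosome level in 10 kb windows (top) and each column minus the mean of the wild-type columns (bottom, log2) against chromosome position in Mb. Black lines are the 3 wild-type columns and red lines the 3 deletion columns. All 3 deletion columns lie above the wild type towards 2.019 Mb, the difference falls beyond it, from a log2 of 0.26 in the window from 2010001 to 0.047 in that from 2040001, and deletion column 2 has narrow dips that are shallower or absent in the others.

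**Figure D4:**
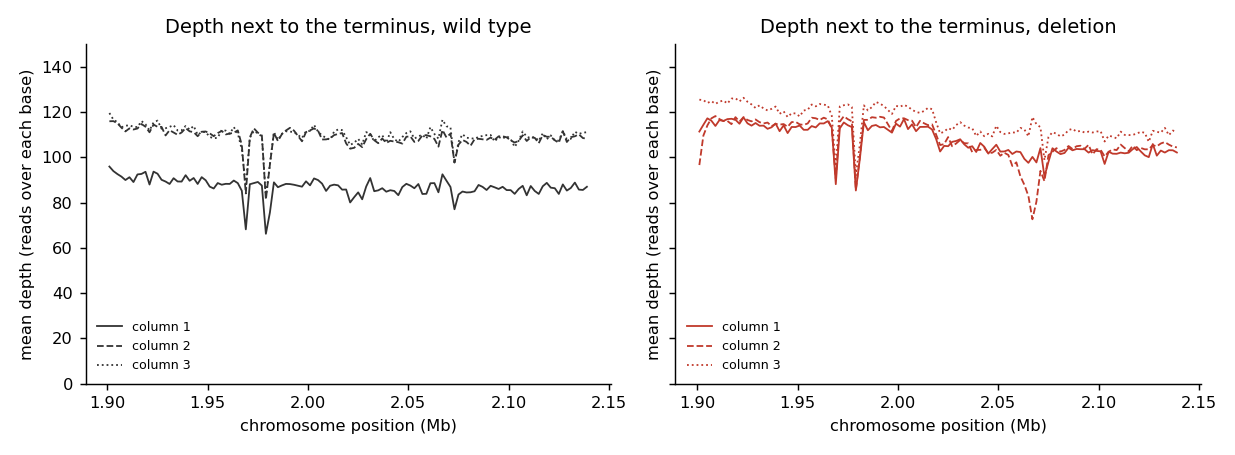
Mean depth in reads over each base (y axis) in 2 kb windows from 1.9 to 2.14 Mb (x axis, Mb), over bases covered in all 6 columns, for the wild type (left) and the deletion strain (right). Lines are the 3 depth columns of each sample. Depth drops near 2.019 Mb in all columns of both strains, and the wild-type columns regain more of the drop by the window from 2040001. Over the regions of 100 kb on either side, the step of converted depth was a log2 of 0.31 in the deletion strain and 0.048 in the wild type.

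Unevenness of depth as deposited, which the ceiling reduces, did not separate the strains on the chromosome. After the broad gradient had been removed, the coefficient of variation over 1 kb windows was 5.65% ± 0.099 (SD over 3 columns) in the wild type. In the deletion strain it was 5.64% ± 0.19. Unlike on the plasmid, no value was computed without the window that holds the lost stretch. In 5 kb windows the values were larger, 7.84% and 7.89%. Depth was 0 in all 3 columns at 52622 bases of the wild-type chromosome, or 1.25%, and at 53518 bases, or 1.27%, of the deletion chromosome. Of these, 52479 bases were empty in both strains. On the plasmid, 0 bases were empty in the wild type and 290 in all columns of the deletion strain.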

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

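Of the values recomputed under other settings, 86 moved by less than the spread of the columns (counts of windows, by less than 1.5 times) and 35 moved by more. This split does not measure robustness. Single columns of a genotype were judged against the SD of those same columns, so some had to move. Counts of risen windows stayed at 0 under a ceiling that hides gains. The quotient of the origin to terminus ratios of the strains stayed within its spread under all alternatives run, and that of the plasmid ratios under all but converted depth. No window rose 2-fold under any alternative on either replicon. Among simulated chromosome windows with a 2-fold gain, 0% passed 2-fold in depth and 18% in converted depth, so this says little about gains. Unless it is named, the cause was not tested. The alternatives with converted depth and all those for the terminus step were chosen after seeing the data. No paired analysis was possible because each genotype has 1 sample, and leaving out a replicate was not possible for the same reason. The alternatives for gene lists, for gene orientation and for base composition were not run. Converted depth gave a plasmid to chromosome ratio of 1.35 in the wild type and 1.41 in the deletion strain, a quotient of 1.05, and origin to terminus ratios of 2.54 and 2.44. Over the origin alone the plasmid ratio was 0.965 and 0.988, and over the terminus alone 1.354 and 1.345. Mean depth gave an origin to terminus ratio of 1.24 in the deletion strain. Column 1 alone gave plasmid ratios of 1.12 and 1.11 and a wild-type origin to terminus ratio of 1.57, and column 3 gave 1.30 for that ratio in the deletion strain. Depth over the lost chromosomal stretch was 94.3% of the median in wild-type column 1 and 0.064% in deletion column 1. Over the plasmid stretch it was 98.1% in wild-type column 3 and 0.24% in deletion column 2. The chromosome had 2 lowered windows at 500 bp, 2 without a depth minimum and 0 at 5 kb, and the plasmid had 0 at 1 kb. In converted depth both counts were 0, since lost bases are left out there. The terminus step between strains was 0.125 in depth as deposited and 0.316 in column 2 of both, against 0.26. The chromosomal coefficient of variation was 7.84% in the wild type and 7.89% in the deletion strain in 5 kb windows, 5.82% in wild-type column 1 and 5.99% in deletion column 2. On the wild-type plasmid it was 1.28% and 1.23% in columns 1 and 3. On the deletion plasmid it was 2.40% in 5 kb windows and 4.93% and 4.96% in columns 2 and 3. The depth ceiling of 152 reads limits copy number values most near the origin, where column medians reached 146 reads, and on the plasmid, where they reached 143 reads.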

Other observations

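The regions and tests below were chosen after the results had been seen, except the search for steps along the chromosome, which was set before its result was known. A second, local rise lay on the clockwise arm of the deletion strain. Converted depth from 1.32 to 1.40 Mb exceeded that of the neighbouring 1.16 to 1.26 and 1.46 to 1.56 Mb by a log2 of 0.053, 0.054 and 0.155 in the 3 deletion columns. In the wild-type columns the values were −0.030, −0.0016 and 0.0052. Over 1300001 to 1400000, deletion column 3 differed from the wild type by a log2 of 0.34, and columns 1 and 2 by 0.10 and 0.14. No genes are named there, since annotation of this assembly was not used here.

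Deletion column 2 had local dips of depth that were shallower or absent in the other columns. Whether DNA was missing there, or reads were fewer for another reason, was not tested. After a running median had been removed from each column, its converted depth lay more than 0.4 (log2) below the mean of the 3 wild-type columns in 22 of 2080 windows of 2 kb, forming 10 regions. Deletion columns 1 and 3 had 0 such windows, as did each wild-type column against the other wild-type columns. The lowest 10 kb windows of the comparison between strains include 2260001 to 2270000, at a log2 of −0.59 in deletion column 2 and −0.19 and −0.041 in columns 1 and 3, and 3660001 to 3670000, at −0.49, −0.18 and −0.16 in the same order.

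Depth dropped locally near 2.019 Mb in both strains, and the wild type regained more of the drop by the 2 kb window from 2040001. The larger step between 100 kb regions on either side in the deletion strain was weighed against technical explanations. For compression by the depth ceiling, the smallest deletion step exceeded the largest wild-type step by a log2 of 0.224 after conversion. This could not decide, since the steps were already apart as deposited and conversion widens steps at these depths. As deposited they were 0.126 to 0.187 in the deletion columns and 0.018 to 0.035 in the wild-type columns. Wild-type columns 2 and 3, with chromosome medians of 133 and 135 reads, had steps of 0.027 and 0.018. The deletion columns had medians of 128, 130 and 136 reads. Columns of like depth are compressed alike, so these deposited steps argue against the ceiling as the source of the difference between these columns. Read number is argued against, since the wild-type columns of like depth lay 0.226 below the smallest deletion step. Nor did the libraries show such steps elsewhere. The largest absolute difference between strains at least 150 kb away was 0.097, against 0.26 here. Without deletion column 2, the column with the local dips, the difference here was 0.232. Relative to the origin, the clockwise side was higher in the deletion strain by a log2 of 0.337 with an SD of 0.19. That region was picked for its excess, and its closest columns were only 0.055 apart. The other side was also higher in the deletion strain, by 0.075 with an SD of 0.19. Late replication of that arm would lower it, but the difference lies within its SD. Extra copies of the clockwise arm and late replication of the other arm both stay open. So do an untested effect of the deletion and a difference between cultures.

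On the chromosome, 10 stretches of at least 2.5 kb had a depth of 0 in all 6 columns. The gene table of the other assembly lists 30 rRNA genes, among them 10 for 5S rRNA. The equal number, 10 stretches for 10 operons, is consistent with the removal of reads that match more than 1 place, a hypothesis formed after the stretches had been seen. If so, depth over these operons says nothing about their copy number in either strain.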
